A study of Homo sapiens with 2 samples.

How the data were processed

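RNA was sequenced from 2 cultures labelled as OVCAR-3, an established human ovarian carcinoma cell line. They were 1 control culture that carried an empty viral vector and 1 culture made to overexpress IGF2BP3, an RNA-binding protein that reads m6A marks. Per the labels' protocols, messenger RNA was captured with oligo(dT) beads, fragmented, and turned into libraries by a method that marks the strand with dUTP and ends with PCR. No molecular identifiers are described, so reads are not independent molecules.

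Whole-number counts per gene were deposited by the authors, per the file headers, for 28038 genes. FPKM values were also deposited by the authors, per the file headers, and a count divided by its FPKM gave a gene length within 0.01 of a whole number in 99.99% of genes when the listed counts were taken as the library total. The log2 fold change that the authors deposited, per the file headers, lay within 0.01 of the log2 ratio of CPM (a gene's counts over the library total, times 1e6) with a prior count of 0.125 in all 28038 genes. The genome build was GRCh38, per the submitters' processing notes; the aligner, the counter, its strand setting and the annotation release are not given in the sources used here. Among counts from 1 to 20, 64.1% were even in the control library and 63.3% in the overexpression library, and 2927 control genes had 2 counts against 1217 with 1. Such a surplus would arise if both mates of a read pair were counted, so intervals for IGF2BP3 and FASN are also given from halved counts, a choice made after seeing the data. All other intervals are from the counts as deposited and would be too narrow in that case.

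The listed counts summed to 43190215 in the control library and 48017861 in the overexpression library. Libraries were scaled by TMM (edgeR 4.0.16 in R 4.3.3), and the difference of a gene was the log2 ratio of CPM plus 1, overexpression over control, among 14157 genes with at least 50 counts over both libraries. Ratios carry 95% exact (Clopper-Pearson) counting intervals from the share of a gene's counts found in each library. These intervals cover counting error only. A count of 3, taken as the floor, equals 0.0692 CPM in the control library and 0.0627 CPM in the overexpression library. With 1 sample per group there is no replicate error, no p-value was computed, and every difference is between these 2 libraries.

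Genes named by size were fixed by rule before the data were examined: IGF2BP3 and FASN, the 15 highest and 15 lowest log2 ratios among genes past the count minimum with a gene symbol and a counting interval on one side of 1-fold, and the 4 members of each list furthest from 0. One gene among the 15 lowest has a copy on each sex chromosome and is not reported here, nor are a few other genes, some of them list members that this rule names. The members of 37 gene lists were fixed at the same time. For each list with at least 3 measured members, the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Members counted as 1.5-fold different, like genes counted as 2-fold different, are so on the scale of CPM plus 1, which understates the difference of low genes. A median was counted as outside the random lists when it fell beyond their central 95%, a bound set after the medians, but not their percentiles, had been seen. Random lists hold unrelated genes, so lists whose genes vary together leave that range more readily than chance alone would give.

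Gene positions, gene types and transcript sequences came from GENCODE release 29 on GRCh38, which held 26424 of the listed gene IDs (94.2%). Alternatives were scaling by library totals or by DESeq2 1.42.0 size factors, the authors' FPKM values plus 1, other pseudocounts, count minimums and fold thresholds, and other random lists; further ones were added after seeing the data. The size rule was tested on simulated data with Poisson noise and 14142 genes past the minimum: 84 of 96 genes changed 3-fold and none of 100 changed 1.5-fold came out at least 2-fold different, and 94.9% of the counting intervals held the true ratio. The simulated counts lacked the surplus of even counts, so that share does not carry over to the deposited counts. In the same simulation 100 of 100 lists of 20 genes shifted by 0.2 lay above the 97.5th percentile, and 5 of 100 unchanged lists lay outside the central 95%. The unchanged lists were drawn at random from the same simulated genes, so about that share is given by construction. It does not carry over to lists whose genes vary together. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.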

Results

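Poly(A) RNA was sequenced from 1 control culture and 1 IGF2BP3-overexpressing culture, both labelled as OVCAR-3, a human ovarian carcinoma cell line. Most listed markers of epithelial cells and of ovarian serous carcinoma were low in both libraries, as given below. The control library held 43190215 counts and the overexpression library 48017861. There was no replicate of either group, so every ratio is between these 2 libraries and the intervals give counting error only.

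The comparison asked which transcripts differ when IGF2BP3 is overexpressed, with FASN, the fatty acid synthase, as the gene that the series title names. IGF2BP3 was 1.96-fold higher in the overexpression library, and FASN was 1.09-fold higher. The genes of cholesterol synthesis and of drug efflux and detoxification were mostly higher in the overexpression library, and targets of TGF-beta and YAP were mostly lower. Most genes differed little, and 96 of the 14157 measured genes differed at least 2-fold.

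IGF2BP3 (ENSG00000136231; GRCh38 chromosome 7, 23310209 to 23470467, minus strand) went from 2944 counts, 67.9 CPM, in the control library to 6376 counts, 133 CPM, in the overexpression library. The counting interval of the 1.96-fold ratio was 1.88 to 2.05, or 1.84 to 2.09 from halved counts. The control library thus already held the transcript, and none of the 500 genes nearest to it in abundance had as high a ratio. Its log2 ratio of 0.96 ranked 58th among all measured genes and fell just short of the 2-fold rule. The authors' deposited table gives a log2 fold change of 0.96 for it.

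FASN (ENSG00000169710; chromosome 17, 82078333 to 82098332, minus strand) had 22083 counts, 510 CPM, in the control library and 26594 counts, 556 CPM, in the overexpression library. Its ratio had a counting interval of 1.07 to 1.11, or 1.06 to 1.12 from halved counts. Of the 500 genes nearest to it in abundance, 81 had a ratio at least as high and 115 a ratio at least as far from 1-fold in either direction. The authors' deposited table lists a log2 fold change of 0.12 for FASN.

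**Figure D1:**
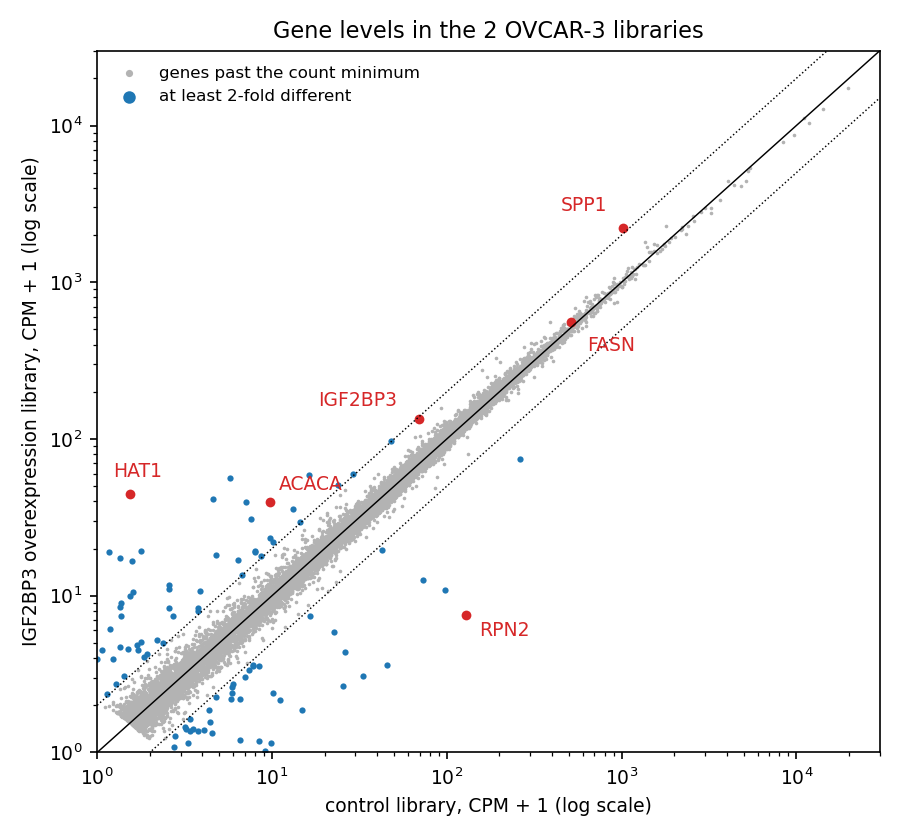
Each point is a gene past the count minimum, with its level in the control library on the x axis and in the overexpression library on the y axis, both as CPM plus 1 on log scales; genes on the Y chromosome are not drawn. The solid line marks equal levels and the dotted lines a 2-fold difference; IGF2BP3 lies near the upper dotted line and FASN, at 510 and 556 CPM, near the solid one.

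Of the fatty acid synthesis and desaturation genes, 16 of 23 measured members were above 0 on the log2 scale and 7 below, with a median of 0.09 at the 99.1st percentile of random lists. ACACA, the acetyl-CoA carboxylase that makes malonyl-CoA, was the member furthest from 0, with 380 counts in the control library and 1847 in the overexpression library, a ratio of 4.40 (3.94 to 4.93). Its log2 ratio was 2.02 on the scale of CPM plus 1 and 1.24 on that of FPKM plus 1. ACACA (chromosome 17, 37084988 to 37406818) has another gene at least 2-fold different within 1 Mb. It was the only member at least 1.5-fold different in either direction. ACSS2 was 1.32-fold higher (1.26 to 1.38), ME1 1.26-fold (1.22 to 1.29) and HSD17B12 1.24-fold (1.16 to 1.34). The citrate lyase ACLY stood at 1.15-fold (1.13 to 1.17) and the desaturase SCD at 1.09-fold (1.07 to 1.10).

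In cholesterol synthesis, 18 of 20 measured genes were higher in the overexpression library, none by 1.5-fold, and the median of 0.23 lay at the 100th percentile. HMGCS1 was 1.47-fold higher (1.42 to 1.51), MSMO1 1.35-fold (1.31 to 1.39), CYP51A1 1.37-fold (1.15 to 1.64) and HSD17B7 1.30-fold (1.22 to 1.39). SREBP pathway regulators and uptake targets had a median of 0.13 over 14 genes, at the 99.5th percentile, with INSIG1 at 0.38, INSIG2 at 0.31, MBTPS2 at 0.26 and ABCA1 at 0.25 on the log2 scale. SREBF1, which encodes a regulator of lipid synthesis genes, was at 71.3 CPM in the control library and 71.2 in the overexpression library. Fatty acid oxidation genes had a median of -0.01 over 23 members, at the 24.7th percentile, with PPARA at 0.22, ACADSB at 0.20, ACAA2 at -0.19 and ACAA1 at 0.16. Fatty acid uptake, activation, lipid droplet and lipolysis genes had a median of 0.05 over 22 members, at the 87.8th percentile, with ACSL4 at 0.40, PLIN4 at -0.33, ACSL6 at -0.27 and MGLL at 0.27; with trends in GC content and gene length removed their median was 0.07, at the 97.9th percentile and outside the random range.

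Drug efflux and detoxification genes had the highest median of any list, 0.27 over 22 members at the 100th percentile, with 20 above 0 and 4 at least 1.5-fold higher. Cholesterol synthesis had the higher median of these 2 lists in 3 alternatives. These were FPKM plus 1 (0.21 against 0.19), a pseudocount of 5 CPM (0.22 against 0.19) and a count minimum of 200 (0.23 against 0.20). The aldo-keto reductases AKR1C1, at 2.14-fold (1.94 to 2.36), AKR1C2, at 3.08-fold (2.15 to 4.5), and AKR1B10, at 3.30-fold (2.20 to 5.08), led the list with the export pump ABCC2, at 1.70-fold (1.63 to 1.76). AKR1C1 and AKR1C2 are near-identical copies, so the value of each is uncertain. Ferroptosis control genes had a median of 0.11 over 17 members at the 99.3rd percentile, with 9 above 0 and 8 below. CHAC1 stood at -0.81, SLC7A11 at 0.48, SAT1 at 0.45 and ACSL4 at 0.40; without a count minimum the list lay within the random range, at the 93.2nd percentile. Matrix protease and invasion genes had a median of 0.18 over 22 members at the 100th percentile, with MMP1 at 0.53, ITGB3 at 0.46, ADAM17 at 0.32 and MMP12 at 0.31. That median was 0.09 with a count minimum of 200 or with none, and 0.10 with FPKM plus 1 or a pseudocount of 5 CPM, in each case above the random range. Interferon-stimulated genes had a median of 0.16 over 32 members at the 100th percentile, and SAMD9, at 0.99, and SAMD9L, at 0.88, were the 2 at least 1.5-fold higher, before OAS2 at 0.50 and IFITM1 at 0.39. Their median was 0.07 with FPKM plus 1 and 0.10 with a pseudocount of 5 CPM, both above the random range. Hypoxia response genes had a median of 0.10 over 21 members at the 98.8th percentile, with EGLN1 at 0.51, PDK1 at 0.41, INSIG2 at 0.31 and EGLN3 at 0.28.

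TGF-beta and YAP targets had the lowest median, -0.22 over 17 genes at the 0th percentile, with 13 below 0. ID2, an inhibitor of DNA binding, was at 0.506 times its control level (0.455 to 0.563), ID1 at 0.674 (0.610 to 0.745), BAMBI at 0.652 (0.518 to 0.819) and THBS1, from 61 and 31 counts, at 0.460 (0.289 to 0.720). The 13 mitochondrially encoded genes had a median of -0.15 at the 0th percentile, 12 of them below 0, with MT-ND2 at -0.24, MT-ND1 at -0.22, MT-CYB at -0.21 and MT-ND4L at -0.20. All listed genes with a symbol that starts with MT- together held 9.0% of the control library's counts and 7.96% of the overexpression library's. Cytosolic ribosomal proteins had a median of -0.08 over 61 genes at the 0th percentile, with 57 below 0. Against this, RPL7A stood at 2.44 and RPS2 at 0.38, while RPS9 was at -0.29 and RPS12 at -0.17. RPL7A, RPS2 and RPS9 were below 10 CPM in both libraries, where the list's median level was 486 CPM in the control library. Nuclear-encoded respiratory chain genes had a median of -0.07 over 37 members at the 0.06th percentile, with UQCRC2 at -0.27, NDUFB8 at 0.20, NDUFA13 at -0.20 and ATP5MC1 at -0.20; matching on length as well moved them to the 2.56th percentile, within the random range. Unfolded protein and integrated stress response genes had a median of -0.07 over 24 members at the 0.62nd percentile, with CHAC1 at -0.81, DDIT3 at -0.54, SLC7A11 at 0.48 and CEBPB at -0.41. Immediate early genes had a median of -0.09 over 24 members at the 0.66th percentile, with FOSB at 0.42, DUSP2 at -0.40, DUSP4 at 0.37 and CCN2 at -0.37, and lay within the random range, at the 4.39th percentile, with matching on length. Wnt and Notch targets had a median of -0.12 over 16 members at the 0.91st percentile. NKD2 stood at -1.19, HEY2 at -0.38, HES1 at -0.36 and HEY1 at -0.32, and NKD2 has another gene at least 2-fold different within 1 Mb. The list lay within the random range with a count minimum of 200, with no minimum and with FPKM plus 1.

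**Figure D2:**
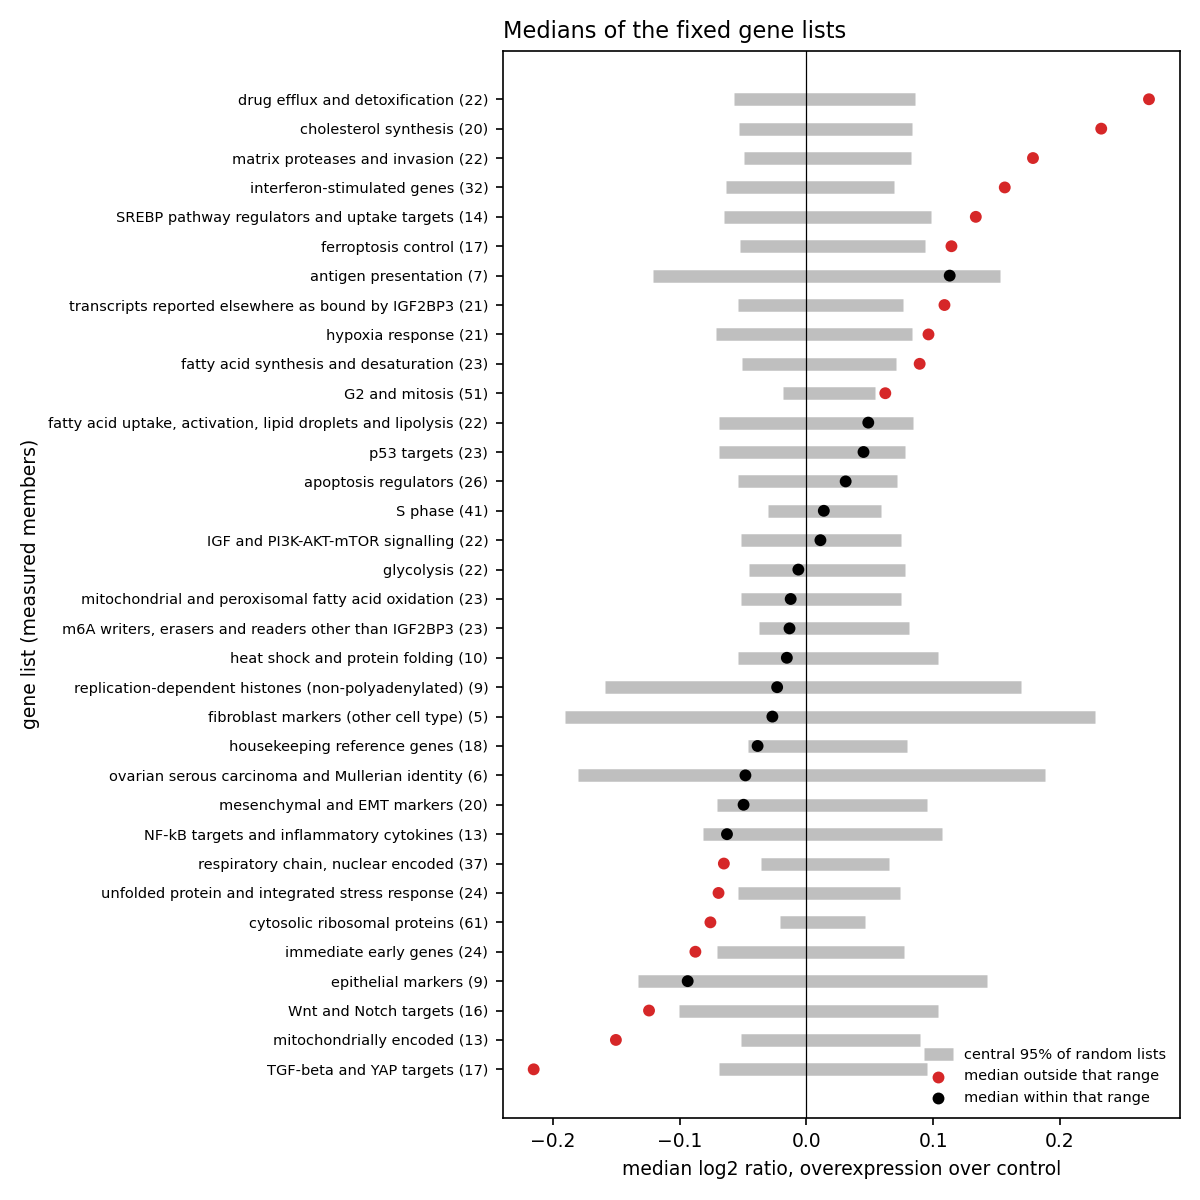
Each row is a gene list with its number of measured members; the dot is the median log2 ratio, overexpression over control, and the grey bar the central 95% of the medians of 10000 random lists matched on expression. Medians outside the bar are red, from -0.22 for TGF-beta and YAP targets to 0.27 for drug efflux and detoxification.

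Transcripts reported elsewhere as bound by IGF2BP3 had a median of 0.11 over 21 genes at the 99.8th percentile, with 15 above 0. The median was 0.07 without a count minimum, and 0.03, at the 91.1st percentile, with trends in GC content and gene length removed. CDK6, a G1 kinase, was 1.85-fold higher (1.72 to 1.99), CCND3 1.20-fold (1.15 to 1.26) and HK2 1.16-fold (1.10 to 1.22). BCL2 was at 0.863 times its control level (0.780 to 0.955), and MYC at 0.929 (0.872 to 0.988). Halved counts would widen these intervals, and that of MYC already ends close to 1-fold. Other m6A writers, erasers and readers had a median of -0.01 over 23 genes at the 15.7th percentile, none of them 1.5-fold different, with RBM15 at 0.24, ZC3H13 at 0.19, YTHDC2 at 0.18 and YTHDF3 at 0.13. IGF and PI3K-AKT-mTOR genes had a median of 0.01 over 22 members at the 54.4th percentile, with IGFBP3 at -0.61, PIK3CA at 0.34 and RICTOR at 0.33.

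G2 and mitosis genes had a median of 0.06 over 51 members at the 98.9th percentile, 36 of them above 0, with SMC4 at 0.30, CENPE at 0.26, CKAP2 at 0.24 and KIF20B at 0.23. S phase genes had a median of 0.01 over 41 members at the 53.4th percentile, with CASP8AP2 at -0.48, UBR7 at 0.38, UNG at -0.28 and ATAD2 at 0.15. Glycolysis genes had a median of -0.01 at the 27.0th percentile, with SLC2A3 at 0.65, ALDOA at -0.54, PFKFB4 at 0.50 and PDK1 at 0.41. ALDOA was below 10 CPM in both libraries. Targets of p53 had a median of 0.05 at the 88.1st percentile, with GDF15 at 0.42, TP53INP1 at 0.36, CDKN1A at 0.29 and RRM2B at 0.26. Apoptosis regulators had a median of 0.03 at the 79.1st percentile, with APAF1 at 0.56, PMAIP1 at 0.25, BCL2 at -0.20 and CASP9 at 0.18. NF-kB targets and inflammatory cytokines had a median of -0.06 over 13 members at the 6.29th percentile, with ICAM1 at 0.72, TRAF1 at 0.40, TNFAIP3 at -0.24 and NFKBIA at -0.22. Antigen presentation genes had a median of 0.11 over 7 members at the 93.0th percentile, with ERAP2 at 0.34, PSMB10 at 0.23, CIITA at 0.18 and ERAP1 at 0.11. That median was 0.03 with a count minimum of 10, 0.02 with FPKM plus 1 and 0.03 with GC and length trends removed. It was -0.05, at the 18.1st percentile, with a count minimum of 200. Heat shock and protein folding genes had a median of -0.02 at the 22.6th percentile, with HSPA4L at 0.21, HSPA8 at -0.08, BAG3 at -0.08 and DNAJB1 at -0.06. Replication-dependent histones, whose transcripts mostly lack poly(A) tails, had a median of -0.02 over 9 members at the 36.7th percentile, with H4C8 at -0.22, H3C10 at 0.14 and H1-4 at -0.13. Housekeeping reference genes had a median of -0.04 over 18 members at the 4.67th percentile, with TFRC at 0.33, CYC1 at -0.19, SDHA at 0.13 and GUSB at -0.11.

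Markers of epithelial cells were low in both libraries. Of 25 epithelial markers chosen, 19 were among the genes listed in the table used here, which holds no gene at 0 counts in both libraries. Of the 19, 15 were below 10 CPM in both libraries and 4 reached that level in at least 1 library. The count minimum was passed by 9, with a median log2 ratio of -0.09 at the 7.69th percentile. That median was -0.02 with a count minimum of 10 or of 200, at the 39.6th and 38.6th percentile, and -0.03 with GC and length trends removed. The adhesion molecule CDH1 had 2 counts in each library, KRT19 had 2 and 0, and EPCAM had 57 and 56. Within this list TJP1 stood at -1.24, OCLN at 1.12, JUP at 0.40 and TJP3 at -0.38. TJP1 and OCLN each have another gene at least 2-fold different within 1 Mb. Of 22 chosen markers of ovarian serous carcinoma and Mullerian identity, 13 were listed, and 12 of these were below 10 CPM in both libraries, among them PAX8 with 28 and 32 counts and WFDC2 with 4 and 0. The 6 measured ones had a median of -0.05 at the 31.5th percentile, with SPON1 at -0.45, CCNE1 at -0.21, BCAM at 0.11 and CD24 at -0.06. Mesenchymal and EMT markers had a median of -0.05 over 20 members at the 7.69th percentile, with TWIST1 at -0.31, TAGLN at -0.29, COL5A1 at -0.29 and S100A4 at 0.28. Most of these markers were low too: of 24 listed, 14 were below 10 CPM in both libraries and 10 reached that level in at least 1 library. Among the latter, VIM, the mesenchymal intermediate filament, was at 2175 CPM in the control library and 2149 in the overexpression library. ZEB1 was at 57.1 and 58.9 CPM. Of the markers of other cell types, fibroblast genes had a median of -0.03 over 5 members at the 36.3rd percentile, with THY1 at -0.19, COL1A1 at -0.17, FBLN1 at -0.03 and COL3A1 at -0.03. A single leukocyte marker, LCP1 at 0.13, and no endothelial marker passed the count minimum. Of the markers of packaging, liver and neural cells, TUBB3 at -0.43 and LIN28B at 0.07 did so.

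In total 54 genes were at least 2-fold higher in the overexpression library and 42 at least 2-fold lower. HAT1, a histone acetyltransferase, had 23 counts in the control library and 2082 in the overexpression library, a ratio of 81.9 (54.5 to 130). BOLA2B followed at a log2 ratio of 4.04, FRG1 at 3.69, the heme oxygenase HMOX2 at 3.42, the bromodomain protein BRD2 at 3.39, MTCH2 at 3.30 and CUTA at 3.18. Further down were NECAP2 at 2.72, WDR73 at 2.71, PIP4P1 at 2.71, TOLLIP at 2.66, the nuclear pore protein NUP160 at 2.48, RPL7A at 2.44, CDR2 at 2.37 and PARP2 at 2.19. On the lower side, RPN2, a subunit of the oligosaccharyltransferase, went from 5563 counts to 313, at 0.0509 times its control level (0.0453 to 0.0571). The DNA repair endonuclease APEX1 had a log2 ratio of -3.65, RCC2 -3.43, CEP20 -3.24, the membrane fusion ATPase NSF -3.16, the isoleucyl-tRNA synthetase IARS1 -3.15, the ubiquitin-like NEDD8 -3.11 and SLC25A24 -3.0. TMEM50B was at -2.82, RNH1 at -2.57, BTN2A1 at -2.44, TMEM14C at -2.37, TOP3A at -2.08 and UBE2A at -1.96. Of the 30 genes at both ends, 17 had another gene at least 2-fold different within 1 Mb, and 4 (BOLA2B, FRG1, RPL7A and NSF) shared at least 20% of their 31-base words with another annotated gene. The count of 96 fell to 45 when genes with such a neighbour were left out, and was 44 on the scale of FPKM plus 1, where the constant weighs more in most genes than on that of CPM plus 1, 209 with a pseudocount of 0.1 CPM and 39 with 5 CPM.

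**Figure D3:**
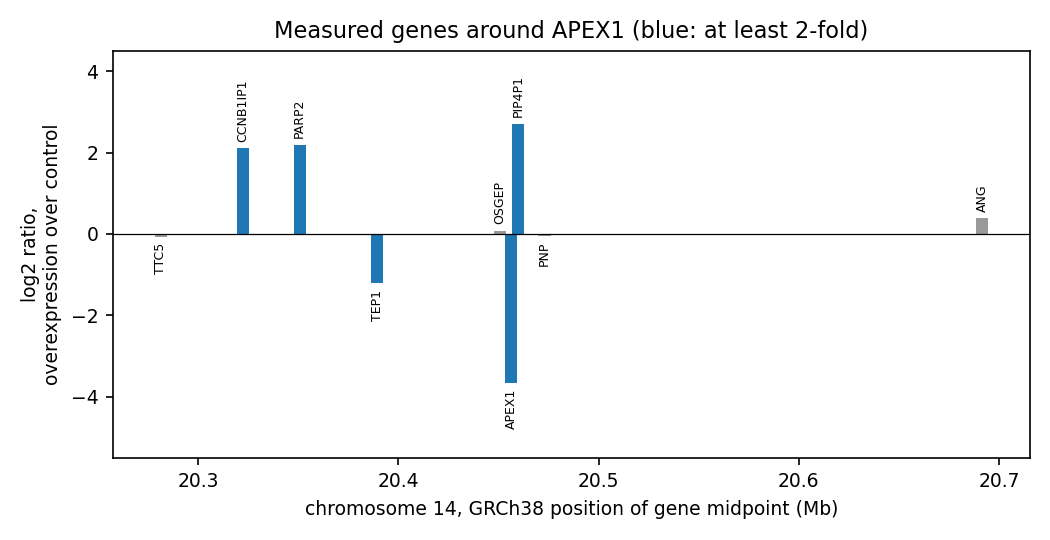
Log2 ratio, overexpression over control, of each measured gene on chromosome 14 around APEX1, at its midpoint in GRCh38; blue bars are at least 2-fold different and grey bars are not. APEX1, at -3.65, lies next to PIP4P1, at 2.71, and the stretch also holds CCNB1IP1, at 2.11, PARP2, at 2.19, and TEP1, at -1.21, while OSGEP, beside APEX1, stands at 0.08.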

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

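IGF2BP3, FASN, ACACA and the lists outside the random range kept their direction under every alternative. Some medians within that range changed sign. Antigen presentation went from 0.113 to -0.053 with a count minimum of 200. With no filter, NF-kB targets went from -0.063 to 0.007 and histones from -0.023 to 0.043. With GC and length trends removed, glycolysis went from -0.006 to 0.035, S phase from 0.014 to -0.011 and IGF and PI3K-AKT-mTOR genes from 0.011 to -0.011. Scaling by library totals or by DESeq2 size factors moved no list across the random range and gave 97 genes at least 2-fold different each. Such scaling shifts a list and its random lists by nearly the same amount, so it could hardly move a percentile and says little about the lists. IGF2BP3 had a log2 ratio of 0.96, against 0.88 as the log2 ratio of FPKM plus 1 and 0.89 with GC and length trends removed; FASN had 0.12, against 0.15 with those trends removed. ACACA had 2.02, against 1.24 with FPKM plus 1 and 1.66 with a pseudocount of 5 CPM. The 96 genes at least 2-fold different, 54 higher and 42 lower, became 44 (28 and 16) on the scale of FPKM plus 1, 209 (116 and 93) with a pseudocount of 0.1 CPM, 39 (23 and 16) with 5 CPM, 235 (144 and 91) at a fold threshold of 1.5, and 45 (29 and 16) without genes that have another such gene within 1 Mb. An added constant acts most on low values by its construction, and FPKM without it has the same ratios between the libraries as CPM by library totals, so the changes of IGF2BP3, of ACACA and of the count of 96 with FPKM plus 1 come from the constant; the cause was not tested for the other changes. Of the 17 lists outside the random range, Wnt and Notch targets fell within it with FPKM plus 1 and matching on FPKM (-0.064), a count minimum of 200 (-0.070) and no filter (-0.068), ferroptosis control with no filter (0.070), and respiratory chain (-0.065) and immediate early genes (-0.088) with random lists matched on length too. Transcripts reported as bound by IGF2BP3 fell within it with GC and length trends removed (0.033), while fatty acid uptake, activation, lipid droplets and lipolysis moved outside (0.072 against 0.049). Fatty acid synthesis, cholesterol synthesis, drug efflux and TGF-beta and YAP targets stayed outside under every alternative run, of which the scalings could hardly have moved them. Restricting to protein-coding genes by a biotype in the files was not run, since the columns used give none; GENCODE types were used instead, giving 88 genes. That alternative, the trend removal and the neighbour rule were chosen after seeing the data. No paired analysis was possible because each group holds 1 sample. Depth limits genes near the count minimum: ABCA1, with 22 and 38 counts, had a ratio of 1.56 (0.902 to 2.78).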

Other observations

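The test of shared sequence and the test of genes near the epithelial markers were set before their results were seen; all other tests and choices of genes in this part came after. Among genes with at least 1000 counts over both libraries that differed at least 2-fold, had no such neighbour within 1 Mb and shared under 20% of their 31-base words with another gene, SPP1, which encodes the secreted matrix protein osteopontin, was the most abundant. It went from 1019 CPM in the control library to 2214 in the overexpression library, a ratio of 2.17 (2.15 to 2.20). GJA1, the gap junction protein connexin 43, was 2.05-fold higher (1.95 to 2.16), MAP2 2.08-fold (1.95 to 2.23), ARHGAP18 2.18-fold (2.02 to 2.35) and SEMA3E 2.18-fold (1.92 to 2.48). GTF2H1, PPFIA1, RBFOX2, NAP1L4 and HAT1 were also higher, and RPN2 and UBE2A lower. This choice of genes did not test whether reads went to alternate copies outside the primary assembly. That stays open for these genes too, among them HAT1, with 23 counts in the control library, and RPN2, with 313 in the overexpression library.

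Some genes that nearly all cells express were almost without counts. Of 63 listed cytosolic ribosomal proteins, 5 were below 10 CPM in both libraries, while the list's median was 486 CPM in the control library. RPL7A was at 0.369 and 6.41 CPM, RPS2 at 1.20 and 1.86, RPS9 at 1.48 and 1.02, and the glycolytic enzyme ALDOA at 3.48 and 2.09 CPM, in the control and overexpression library.

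Genes at least 2-fold different lay close to one another: 51 of the 94 with a position had another within 1 Mb, against a median of 12 and at most 28 in 1000 random sets matched on expression. Of 32 adjacent pairs within that distance, 16 went the same way and 16 opposite ways. The other measured genes within 1 Mb had a median log2 ratio of -0.00094 in the direction of their neighbour (quartiles -0.10 and 0.10). These values argue against wide copy-number differences between the cultures as the common source for these genes. That median left out genes at least 2-fold different and pooled all regions. A copy-number difference at a single region or over few genes was therefore not tested. A gene near 2-fold genes of opposite direction entered with both signs, which draws the median toward 0 but not the quartiles. Other regions were not looked at. Sequence shared with another gene of the GENCODE release used here was not the main source either. Of the genes, 19.1% shared at least 20% of their 31-base words, 18 genes against 9 to 21 in random sets. Listed gene IDs outside that release were not searched, so sharing with those genes was not tested. Sequences outside the primary assembly were not searched, so an assignment of reads to alternate copies of a region stays open as an untested candidate explanation. An effect of IGF2BP3 overexpression cannot be told apart from it by the count of 51, because each group holds 1 library.

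Of 34 lists with at least 3 measured members, 17 lay outside the central 95% of random lists, 10 above and 7 below, where 1.7 would be expected of unrelated genes. The libraries did differ with sequence: the median log2 ratio went from 0.07 in the fifth of genes with the lowest GC content to -0.05 in the highest, and from -0.03 in the shortest to 0.06 in the longest. With both trends removed, 16 of the 17 lists stayed outside and 1 further list (fatty acid uptake, activation, lipid droplets and lipolysis) moved outside, which argues against these trends as the whole source. Whether the 17 displaced lists follow from IGF2BP3 overexpression or from another difference between the cultures cannot be told apart, because each group holds 1 library.

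Of the 25 epithelial and 22 ovarian serous markers chosen, 32 were among the listed genes and the others were not analysed here. Of the 32, 4 reached 10 CPM in both libraries and 17 were below the count minimum, while the labels name an ovarian carcinoma line. Around those 17 markers, 70% of the 10 nearest listed protein-coding genes passed the minimum, at the low end of the range of random genes (70% to 85.3%). The listed genes leave out any gene at 0 counts in both libraries, so genes without reads could not appear among these neighbours. The test therefore cannot decide on a loss of all reads in these regions, and a loss gene by gene was not tested. A hypothesis is that the cells differ from those the labels name, by identity or by a change of state in culture. The 4 markers at that level cannot be told apart from a normal profile of the line, because no reference profile was used here. No biological explanation was tested, since both groups show the pattern.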
